A study of Panax ginseng with 12 samples.

How the data were processed

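RNA of Panax ginseng embryogenic calli was measured in 12 libraries, per the labels total RNA made into Illumina libraries. The calli were kept at 5 °C or 20 °C for 2, 4 or 6 days, with 2 libraries for each temperature and day. The replicate numbers in the titles are 1 and 3 at day 2, 1 and 2 at day 4, and 2 and 3 at day 6. Nothing in the labels says that replicates are separate cultures, and if they are not, the p-values measure only the spread between these samples. All 12 libraries could be placed in a group from their titles and were used.

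The deposited table gives TPM values per assembled gene, made by the authors, and the unit was read from the values, since no header states it. Each library's deposited TPM sum lies below the full scale of the unit, and no gene has a highest value of 6 or less, so genes were dropped before deposit. Per the submitters' processing notes the tools were cutadapt, FastQC, Salmon and edgeR, and their roles, order and versions are not given in the sources used here. Per the file headers the genes carry Trinity identifiers, which belong to an assembly made from reads, with a length and protein annotation. The assembly settings are not given in the sources used here. The table holds 44953 genes with a median length of 750 bases, 10144 of them under 300 bases. A protein annotation is given for 28432 genes and a Swiss-Prot hit for 19835, which share 10426 distinct hits. Symbols in the text come from these best hits, so several genes can share a symbol, and how reads were divided between near-identical genes is unknown. No read counts are held, so depth per library and the precision it gives are unknown.

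The plan, fixed before the data were examined, assumed estimated counts and a count model. The table held TPM, so the test the plan named for normalized values was used. Values were taken as log2(TPM + 1), genes with at least 1 TPM in at least 2 libraries were kept (353 of 44953 were dropped), and limma 3.58.1 in R 4.3.3 was fitted to the 6 groups with a variance trend and equal library weights. No scaling between libraries was added to TPM. The comparisons were cold against control at each day, the mean of the 3 daily differences, a test that the 3 differences are equal, and tests of change over days within each temperature. P-values were adjusted over genes by Benjamini-Hochberg, with a false discovery rate of 0.05. The R package data.table (version 1.17.8) handled the values, and figures were drawn with python 3.11.15 and matplotlib 3.10.9.

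Gene lists were fixed with the plan as word patterns on the annotation and cover cold response, protection, metabolism, hormones, the clock, growth and markers of other cell types. Of 27 lists, 26 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with a correlation estimated per list, and with fry, adjusted over lists within a comparison. The seed storage list had only an oleosin gene (OL2, log2 difference 0.59, SE 1; limma, Benjamini-Hochberg adjusted p = 0.7) and a 12S storage protein gene (CRD, -0.37, SE 0.18; limma, Benjamini-Hochberg adjusted p = 0.16). GO and KEGG sets from the table's own annotation with at least 20 members were tested in the same way.

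Genes to name were chosen by a rule fixed with the plan. For each list it takes the 2 largest rises and the 2 largest falls among called members for the mean effect. For each day it takes the 5 largest rises and 5 largest falls among called genes whose cold libraries lie both above or both below the controls, and for the day by temperature test and the change over days in control the 5 lowest p. It adds the most expressed member of the cold transcription factor, dehydrin, RNA chaperone and ginsenoside lists. Named genes other than the most expressed members need at least 5 TPM in the higher group or arm, a floor the plan had set in scaled counts, and those named for a day or an interaction need an informative protein name.

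The scripts were tested on simulated libraries with the real means and spreads of 44600 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For the mean effect 21% of the 2-fold and 76% of the 4-fold changes were recovered, with 6 false among 103 calls. Recovery of 2-fold and 4-fold changes was 0% and 5% at day 2, 1% and 9% at day 4, and 0% and 9% at day 6. In the simulation the daily comparisons thus missed most changes of this size. The adjusted cutoff depends on the share of genes that change. The real data had a far larger share called (8.38% at day 4 and 23.3% for the mean), so recovery there can differ and is unknown.

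Alternatives tried were another pseudocount, other filters, a 2-fold threshold, the replicate number as a block, the 4 libraries of a day alone, genes summed by Swiss-Prot hit, and each library left out in turn. Added later were quantile normalization, median ratio scaling, limma without trend, array weights, and a fit without cold day 2 replicate 3 and cold day 6 replicate 3. The planned fits of count models need counts and were left out. Raw reads were not analysed here.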

Results

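Embryogenic calli of Panax ginseng, the plant whose roots are the source of ginsenosides, were kept at 5 °C (cold) or at 20 °C (control), and RNA was sequenced on days 2, 4 and 6. An embryogenic callus is a mass of cultured plant cells that can form somatic embryos. Each temperature and day had 2 libraries, which made 6 groups and 12 libraries. The table held TPM values for 44953 assembled genes, of which 44600 passed a low filter and were tested. Library totals lay between 873298 and 929555 TPM, and median TPM per library between 6.5 and 8.59. TPM keeps no read number, so the depth of each library is unknown and no counting interval can be given. No genome was used here, so the genes carry assembly identifiers and no chromosome positions.

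The first principal component, with 32.6% of the variance, separated the 6 cold libraries (15.4 to 136) from the 6 control libraries (-111 to -52.1). The cold library nearest to the controls was cold day 6 replicate 3, at 15.4, while its partner cold day 6 replicate 2 lay at 90.6. Cold day 2 replicate 3 stood apart on the second component, at 138 against 32 for replicate 1, and had the highest median TPM (8.59) and the lowest share of TPM in its top 50 genes (6.84%). Pearson correlations across genes of log2(TPM + 1) were 0.81 to 0.925 (median 0.864) between libraries of the same group. They were 0.779 to 0.903 (median 0.851) between days at the same temperature and 0.678 to 0.861 (median 0.768) between temperatures. Libraries of the same day were thus hardly more alike than those of other days. Controls tended to group across days instead. Day 2 replicate 1, day 4 replicate 1 and day 6 replicate 3 had r = 0.891 to 0.896 with each other. Day 2 replicate 3, day 4 replicate 2 and day 6 replicate 2 had 0.867 to 0.895, against 0.81, 0.88 and 0.848 within a day. These 2 sets were seen in the values, the labels do not explain them, and no fit included them. Control day 2 replicate 1 had r = 0.81 with its partner and 0.796 to 0.896 with controls of other days. Genes are not independent replicates.

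**Figure D1:**
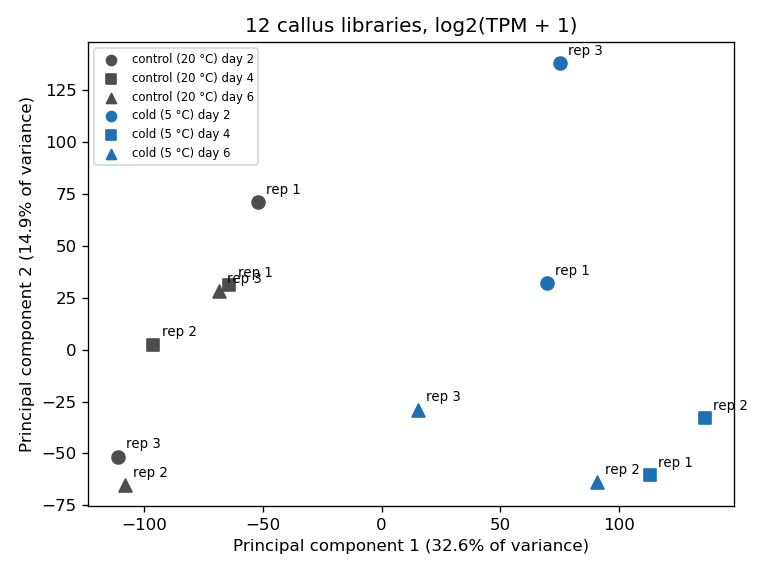
First and second principal components of log2(TPM + 1) for the 12 libraries, with the share of variance on each axis. Colour gives the temperature, the symbol gives the day and the text gives the replicate number. All 6 cold libraries lie to the right of the 6 control libraries, and cold day 6 replicate 3 (15.4 on the first component) is the cold library nearest to them.

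The comparison of the 6 cold with the 6 control libraries, as the mean of the 3 daily differences, asked which genes differed under cold across the days. Among the genes called higher in cold were 19 of 62 cold transcription factors and 13 of 29 dehydrin, LEA and COR genes, and among those called lower were 104 of 315 genes of DNA replication and the cell cycle and 58 of 203 of the cell wall. As groups, these lists were called by camera with a preset correlation and not with an estimated one (adjusted p = 0.28 to 0.32 with an estimated correlation). ZAT6 (TRINITY_DN17580_c0_g2), a zinc finger transcription factor of stress responses, was at 18.3 ± 10.3 TPM in control and 239 ± 127 TPM in cold (SD, n = 6). Its log2 difference was 3.43 (SE 0.36; limma, Benjamini-Hochberg adjusted p = 0.00057). A putative dehydrin (TRINITY_DN23807_c0_g1), of a family that protects cells against loss of water, was at 656 ± 329 TPM in control and 3630 ± 1640 TPM in cold (SD, n = 6). Its log2 difference was 2.46 (SE 0.37; limma, Benjamini-Hochberg adjusted p = 0.0019). ETG1 (TRINITY_DN20488_c1_g1), a partner of the replicative helicase, fell from 24.8 ± 15.7 to 4.23 ± 2.81 TPM (SD, n = 6). Its log2 difference was -2.24 (SE 0.33; limma, Benjamini-Hochberg adjusted p = 0.0019).

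In all, 10384 of 44600 genes (23.3%) were called at a false discovery rate of 0.05, 5050 higher and 5334 lower in cold. This balance depended on scaling, with 5821 higher and 4894 lower after median ratio scaling and 5502 and 5246 after quantile normalization. Of these, 3282 rose and 3084 fell by at least 2-fold. Of the called genes, 9596 (92.4%) had the same sign on all 3 days, which their choice by the mean of those days in part builds in. In 3008 of the called genes the 6 cold and the 6 control values did not overlap. Over all tested genes the arms did not overlap in 3171 (7.11%), where chance gives 0.22%. The count was 5586 without cold day 6 replicate 2, 5749 without cold day 4 replicate 2 and 6703 without control day 4 replicate 2. A fixed rule chose genes to name, and of the 88 it chose that were called for the mean effect, 62 kept their call in each of the 12 fits without 1 library and all 88 kept their sign. The genes given as rising or falling in the following paragraphs are among the 62 unless a value without a library is given. Most of the 88 were chosen for large changes in these same libraries, so their kept sign says little about stability. All log2 differences are on the log2(TPM + 1) scale, which understates the change of genes with low TPM.

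Among the cold transcription factors (CBF/DREB, ICE, CAMTA and ZAT families), 19 of 62 tested members rose, 1 fell and 42 were not called (22 and 2 adjusted over the list alone). ZAT6 led the group, and ZAT11, of the same family, rose by 2.66 (SE 0.66), with an adjusted p of 0.052 without cold day 4 replicate 1 and 0.056 without cold day 6 replicate 2 (limma, Benjamini-Hochberg; 0.016 with all libraries). Of the dehydrin, LEA and COR proteins, 13 of 29 rose, 1 fell and 15 were not called (15 and 1 adjusted over the list alone). Dehydrin 1 (TRINITY_DN17283_c2_g1) rose by 3.79 (SE 0.47), from 3.72 ± 3.22 to 67 ± 61.4 TPM (SD, n = 6), and a late embryogenesis abundant protein similar to At1g64065 rose by 2.50 (SE 0.39). The member that fell was RD21B (TRINITY_DN21748_c0_g1), at -0.70 (SE 0.16), a cysteine protease and not a dehydrin. When genes with the same Swiss-Prot hit were summed, RD21B turned to 0.504. None of 25 RNA chaperones rose, 2 fell and 23 were not called (0 and 2 adjusted over the list alone). RZ1C stood at -0.67 (SE 0.16) and a glycine-rich RNA-binding protein (TRINITY_DN24783_c1_g1) at -0.99 (SE 0.18), which turned to 0.356 when summed by Swiss-Prot hit. The most abundant member (TRINITY_DN19832_c1_g4) was at 3090 ± 777 TPM in control and 4510 ± 2770 TPM in cold (SD, n = 6) and was not called (limma, Benjamini-Hochberg adjusted p = 0.46).

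Sugar genes moved in both directions, with 34 of 102 members of the raffinose, trehalose and starch list rising, 13 falling and 55 not called (45 and 18 adjusted over the list alone). Genes for soluble acid invertase INV*DC4, which splits sucrose into glucose and fructose in the vacuole, rose by 2.99 (SE 0.47; TRINITY_DN23092_c0_g1) and 2.72 (SE 0.43; TRINITY_DN32151_c0_g5). RFS2 (TRINITY_DN28032_c0_g4), named for raffinose synthesis, fell from 57.8 ± 19.9 to 11.2 ± 11.7 TPM (SD, n = 6), a log2 difference of -2.61 (SE 0.34). The trehalose-phosphate phosphatase gene TPPG fell by 1.59 on the log2 scale (SE 0.29). In proline metabolism, 2 of 13 rose, none fell and 11 were not called (2 and 0 adjusted over the list alone). Both are genes for pyrroline-5-carboxylate synthase, the first enzyme of proline synthesis, with log2 differences of 1.87 (SE 0.34) and 1.17 (SE 0.24). Both calls were lost when genes were summed by Swiss-Prot hit (adjusted p = 0.15 and 0.25; limma, Benjamini-Hochberg). The clock list was mostly higher or not called, with 21 of 42 rising, 1 falling and 20 not called (23 and 1 adjusted over the list alone). The morning clock gene LHY rose by 2.18 (SE 0.35) and APRR3 by 2.15 (SE 0.28), from 9.97 ± 3.58 to 49.7 ± 22.5 TPM (SD, n = 6), while APRR7 fell by 1.37 on the log2 scale (SE 0.25).

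Signalling genes for abscisic acid, the hormone of water stress, included 12 of 59 that rose, 3 that fell and 44 not called (14 and 3 adjusted over the list alone). The phosphatase gene PP2CA rose by 2.44 (SE 0.33), and MHZ4, needed for abscisic acid synthesis, fell by 1.23 on the log2 scale (SE 0.23). Of 121 calcium signalling genes, 18 rose, 9 fell and 94 were not called (18 and 8 adjusted over the list alone). The calcium sensor gene CML28 (TRINITY_DN19409_c0_g1) rose by 2.32 (SE 0.19; limma, Benjamini-Hochberg adjusted p = 0.00024). CBL9 rose by 1.63 (SE 0.40), and the kinase gene CIPK23 fell by 1.16 on the log2 scale (SE 0.24). Ethylene and jasmonate genes split into 27 rises, 22 falls and 113 not called of 162 (29 and 23 adjusted over the list alone), with ERF010 at 3.26 (SE 0.42) and ERF13 at -2.38 (SE 0.38). Of 165 auxin and cytokinin genes, 15 rose, 34 fell and 116 were not called (16 and 39 adjusted over the list alone). SAUR32 rose by 2.61 (SE 0.35) and the cytokinin response regulator ARR4 by 1.71 (SE 0.36), and AUX22D fell by 2.08 on the log2 scale (SE 0.49).

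Genes for DNA replication and the cell cycle were mostly lower or not called, with 104 of 315 falling, 10 rising and the rest not called (112 and 14 adjusted over the list alone). Beside ETG1, KIN7A, a kinesin of cytokinesis, fell by 2.31 on the log2 scale (SE 0.47). KIN13A rose by 1.01 (SE 0.18), and a gene similar to cyclin-dependent kinase F-4 also rose. In cell wall remodelling, 58 of 203 fell, 10 rose and 135 were not called (75 and 12 adjusted over the list alone). The arabinogalactan protein gene FLA9 fell from 70.5 ± 46.8 to 7.73 ± 8.83 TPM (SD, n = 6), a log2 difference of -3.29 (SE 0.71). EXPB2, an expansin that loosens walls, fell by 2.50 on the log2 scale (SE 0.56). Another expansin gene, EXPA10, rose by 2.19 (SE 0.45) and the pectinesterase gene PECS-2.1 by 2.90 (SE 0.50). Summed by Swiss-Prot hit, PECS-2.1 (adjusted p = 0.17) and KIN13A (0.059) were not called (limma, Benjamini-Hochberg). Of 189 heat shock proteins and chaperones, 53 fell, 18 rose and 118 were not called (57 and 19 adjusted over the list alone). HSP90-7, the HSP90 of the endoplasmic reticulum, fell from 106 ± 78.4 to 20.8 ± 14.4 TPM (SD, n = 6). The plastid HSP90-5 rose from 6.02 ± 2.62 to 18.8 ± 3.88 TPM (SD, n = 6) but stood at -0.160 when summed by Swiss-Prot hit. For the co-chaperone ATJ20 one assembled gene rose by 1.39 (SE 0.21; TRINITY_DN18589_c1_g1) and another fell by 2.24 on the log2 scale (SE 0.30; TRINITY_DN18589_c1_g4). Their sum with other genes of that hit stood at 0.879. Ribosomal protein genes had 43 falls, 14 rises and 356 not called (25 and 9 adjusted over the list alone). The members that rose most were 2 genes for ubiquitin fused to ribosomal protein L40 (UBICEP52-7), at 3.53 (SE 0.43) and 2.69 (SE 0.40), which also supply ubiquitin.

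Of 46 ginsenoside and triterpene synthesis genes, none rose, 6 fell and 40 were not called, and 1 fell when adjusted over the list alone. A gene for squalene synthase (TRINITY_DN12148_c0_g1), which makes the precursor of triterpenes, fell from 26.2 ± 5.74 to 12 ± 4.09 TPM (SD, n = 6), a log2 difference of -1.09 (SE 0.22; adjusted p = 0.068 when summed by Swiss-Prot hit; limma, Benjamini-Hochberg). The most abundant member, protopanaxadiol 6-hydroxylase (TRINITY_DN28175_c1_g2), which leads to protopanaxatriol ginsenosides, was at 443 ± 181 TPM in control and 267 ± 101 TPM in cold (SD, n = 6) and was not called (log2 difference -0.73, SE 0.29; limma, Benjamini-Hochberg adjusted p = 0.087). Among 94 phenylpropanoid and flavonoid genes, 9 rose, 13 fell and 72 were not called (9 and 13 adjusted over the list alone). The dioxygenase gene At5g05600 (TRINITY_DN16285_c0_g1) rose by 3.63 (SE 0.35) and 4CLL9 fell by 1.52 on the log2 scale (SE 0.27). At5g05600 is in the list by a word match, which does not show a role in flavonoid synthesis. Summed with other genes of its Swiss-Prot hit, At5g05600 was not called (adjusted p = 0.99; limma, Benjamini-Hochberg).

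Antioxidant enzyme genes split into 10 rises, 12 falls and 48 not called of 70 (11 and 13 adjusted over the list alone). The glutathione peroxidase gene GPX6 rose by 1.58 (SE 0.22), and the superoxide dismutase gene FSD2 fell by 1.54 on the log2 scale (SE 0.26). Of 24 glutathione S-transferases, 8 rose, 2 fell and 14 were not called (9 and 3 adjusted over the list alone). An abundant member (TRINITY_DN32085_c2_g1) went from 156 ± 46 to 477 ± 167 TPM (SD, n = 6). Of 32 class III peroxidases, 6 rose, 2 fell and 24 were not called (6 and 2 adjusted over the list alone), with poxN1 at 3.14 (SE 0.45). The list of fatty acid desaturases and phospholipases had 11 rises, 10 falls and 64 not called of 85 (13 and 12 adjusted over the list alone). Its median log2 difference (-0.0924) and mean (0.0167) differed in sign. The plastid desaturase gene FAD4 rose by 2.51 (SE 0.39). The most abundant of the falling delta-12 desaturase genes, FAD2 (TRINITY_DN26830_c0_g1), was at 1090 ± 612 TPM in control and 470 ± 220 TPM in cold (SD, n = 6). It had an adjusted p of 0.051 without cold day 4 replicate 2 (limma, Benjamini-Hochberg; 0.013 with all libraries). Summed by Swiss-Prot hit, FAD4 (adjusted p = 0.52) and FAD2 (0.17) were not called (limma, Benjamini-Hochberg). Of 79 pathogenesis-related proteins, 12 rose, 10 fell and 57 were not called (14 and 11 adjusted over the list alone). Chitinase Cht10 stood at 2.62 (SE 0.54) and the thaumatin-like gene TL1 at -1.87 (SE 0.26). Of 42 photosynthesis genes, 7 rose, 3 fell and 32 were not called (8 and 3 adjusted over the list alone). CAB8 stood at 1.63 (SE 0.29) and psbB, a photosystem II core gene encoded in the plastid, at -2.50 (SE 0.25).

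Of 14 embryogenic callus regulators, 3 rose, 1 fell and 10 were not called (3 and 1 adjusted over the list alone), and the list's median (-0.0288) and mean (0.162) differed in sign. The receptor kinase genes SERK2 (0.98, SE 0.31) and SERK1 (-0.50, SE 0.16) went opposite ways, but SERK2 kept its call in only 3 and SERK1 in only 2 of the 12 fits without 1 library. Adjusted p reached 0.11 for SERK2 without cold day 6 replicate 2 and 0.11 for SERK1 without control day 6 replicate 2 (limma, Benjamini-Hochberg), and SERK2 had 0.24 when summed by Swiss-Prot hit. Of 37 flowering and vernalization genes, 4 rose, 1 fell and 32 were not called (2 and 0 adjusted over the list alone). Of 21 xylem markers none rose, 1 fell and 20 were not called (0 and 0 adjusted over the list alone). Of 19 epidermis and cuticle markers, 3 rose, 1 fell and 15 were not called (4 and 2 adjusted over the list alone), with KCS7, an enzyme of very long fatty acids, at 1.35 (SE 0.32) and a list median of 0.523. The epidermis member that fell, WAXY, makes starch. Both seed storage and oil body genes in the table, for oleosin and a 12S storage protein, were not called, and 2 members were too few for a list test.

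Against all other genes, camera with a preset correlation of 0.01 called 8 of 26 lists. By camera the clock (adjusted p = 2.3e-07), dehydrin (1.6e-06), cold transcription factor (2e-04), sugar (4e-04) and abscisic acid (0.014) lists were higher in cold, and the cell cycle (1.6e-06), cell wall (7.7e-05) and heat shock (0.0049) lists were lower. All 8 camera calls were lost with a correlation estimated per list. The clock, dehydrin, sugar and cell cycle lists had adjusted p = 0.28 with an estimated correlation by camera, and the cold transcription factor and cell wall lists adjusted p = 0.32 with an estimated correlation. By camera heat shock had adjusted p = 0.34 and abscisic acid adjusted p = 0.41 with an estimated correlation. The estimates were 0.032 (sugar) to 0.14 (clock and dehydrin) in the called lists. This form of camera has only the residual degrees of freedom of 12 libraries in 6 groups, so its power is low. For the calcium list, with an estimate of 0.0064, below the preset one, camera adjusted p still rose from 0.21 to 0.4. The losses therefore do not show whether correlation between members accounts for the calls. The rotation test fry, which asks whether a list moves on balance one way and does not compare it with other genes, called 10 lists, those 8 and the calcium (0.032) and ethylene and jasmonate (0.041) lists. The lists camera did not call had adjusted p of 0.056 (ribosomal), 0.058 (ginsenoside), 0.11 (glutathione S-transferases), 0.21 (calcium; auxin and cytokinin), 0.22 (xylem), 0.24 (epidermis), 0.30 (flowering), 0.33 (ethylene and jasmonate), 0.34 (proline), 0.35 (peroxidases; photosynthesis), 0.61 (antioxidants; pathogenesis-related; embryogenic), 0.63 (phenylpropanoids), 0.69 (RNA chaperones) and 0.92 (desaturases).

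**Figure D2:**
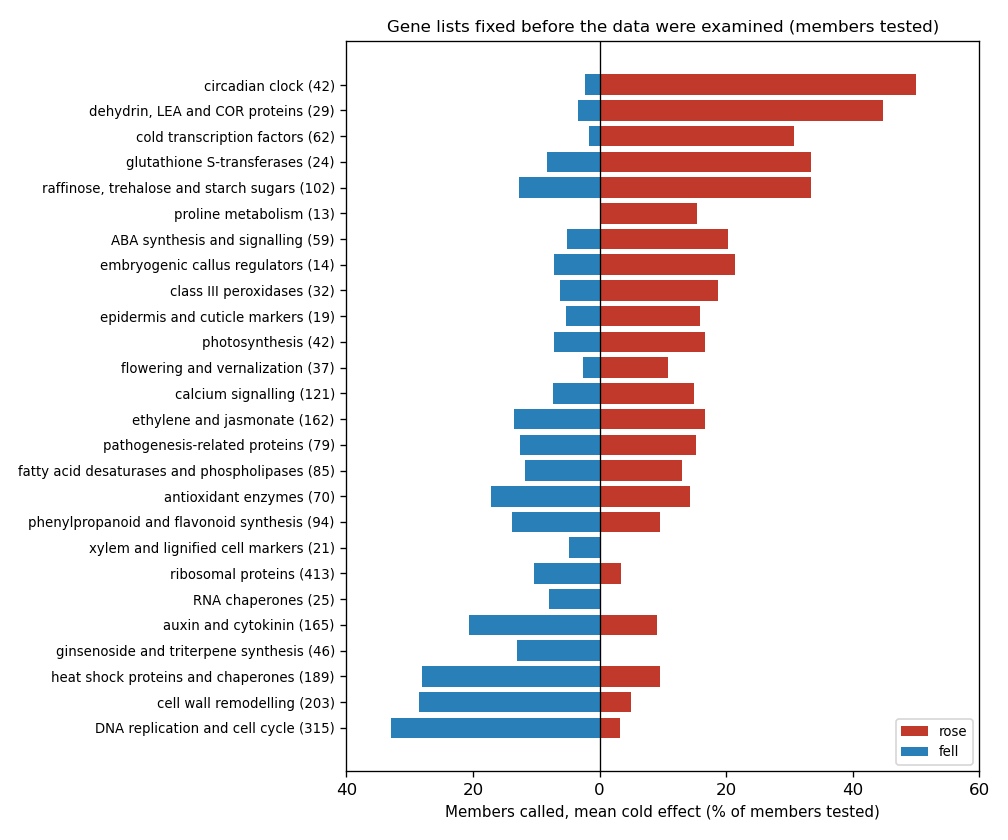
Share of each gene list's tested members that rose (to the right) or fell (to the left) for the mean cold effect, in percent of members tested, with the number tested in brackets. The clock list has 21 rises and 1 fall among 42 members, and the cell cycle list 10 rises and 104 falls among 315.

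At day 2, the annotated genes that rose most in cold against control calli were DREB1A, At3g14260, ZAT6, ERF1A and IQM2, and the largest rise of all was in a gene without annotation (TRINITY_DN18933_c3_g1, 7.28). DREB1A (TRINITY_DN12825_c0_g2), a C-repeat binding factor of the cold response, went from 0.075 ± 0.0495 to 24.7 ± 10.1 TPM (SD, n = 2), a log2 difference of 4.52 (SE 0.53; limma, Benjamini-Hochberg adjusted p = 0.0048). The LURP-one-related gene At3g14260 (TRINITY_DN21645_c0_g2) went from 4.49 ± 0.262 to 149 ± 36.9 TPM (SD, n = 2), a log2 difference of 4.75 (SE 0.41; limma, Benjamini-Hochberg adjusted p = 0.002). ZAT6 rose by 4.77 (SE 0.62), the ethylene response factor gene ERF1A by 4.54 (SE 0.45) and IQM2, a calmodulin-binding protein gene, by 4.43 (SE 0.58). Among the annotated genes the rule could name, the largest falls were in GH3.1 (-4.42, SE 0.76) and LBD29 (-4.01, SE 0.67). The product of GH3.1 joins auxin to amino acids, and LBD29 is a transcription factor of auxin-induced organ and callus formation. RFS2 (-3.31, SE 0.59), the dirigent protein gene DIR2 (-2.94, SE 0.56) and BHLH18 (-2.85, SE 0.55) fell too. Of the cold transcription factors 9 of 62 rose and none fell (13 and 1 adjusted over the list alone), and of the ethylene and jasmonate genes 10 of 162 rose (18 and 1 adjusted over the list alone). Of the sugar genes 8 of 102 rose and 1 fell (14 and 4 adjusted over the list alone) and of the calcium genes 7 of 121 rose (10 and 0 adjusted over the list alone). No cell cycle or cell wall gene was called, though camera placed both lists below other genes (adjusted p = 2.4e-06 and 0.028; adjusted p = 0.41 and 0.63 with an estimated correlation).

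At that day 786 genes were called, 658 higher and 128 lower (83.7% higher), and 71.2% were higher after quantile normalization. Besides the cell lists, camera called the clock (8.1e-05), cold transcription factor (0.00094) and dehydrin (0.0015) lists as higher and the heat shock list (0.00038) as lower, each with adjusted p = 0.41 with an estimated correlation. Without 1 library the count was 15 (cold day 2 replicate 1), 90 (control day 2 replicate 3), 180 (cold day 2 replicate 3), 355 (cold day 4 replicate 2), 371 (cold day 4 replicate 1) and 486 (control day 2 replicate 1). DREB1A and At3g14260 alone of the 10 named genes kept their call in all 12 such fits. ZAT6 (adjusted p = 0.076), ERF1A (0.054) and IQM2 (0.081) lost it without cold day 2 replicate 1 (limma, Benjamini-Hochberg), and the 5 named falls lost theirs without control day 2 replicate 3 or either cold day 2 library (highest adjusted p 0.096 to 0.16). DIR2 (0.054 and 0.055) and BHLH18 (0.052 in each) also lost theirs without cold day 4 replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p). Summed by Swiss-Prot hit, DREB1A (adjusted p = 0.083), GH3.1 (0.18), DIR2 (0.5) and BHLH18 (0.14) were not called (limma, Benjamini-Hochberg). The count was 453 with a pseudocount of 0.1, 1234 without the variance trend, 182 with array weights, 77 without both cold libraries that stood apart and 0 when only the 4 libraries of that day were fitted.

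At day 4, the median log2 difference of all genes was -0.16, against -0.032 after median ratio scaling, and log2 differences of single genes and list medians at this day are given relative to that median. The calls, the counts of rises and falls and the adjusted p values were not shifted and test the TPM difference against 0. The dehydrin list lay above other genes by camera with a preset correlation, with 11 of 29 members rising and none falling (16 and 1 adjusted over the list alone) and a median of 1.77 relative to all genes (camera adjusted p = 3.1e-07, and adjusted p = 0.37 with an estimated correlation). Clock genes followed, with 14 of 42 rising and 1 falling (24 and 1 adjusted over the list alone) and a median of 1.26 (camera adjusted p = 1.3e-09, and adjusted p = 0.37 with an estimated correlation). A putative methyltransferase gene (DDB_G0268948) was 6.76 above the median (SE 1.3), from 1.9 ± 0.785 to 278 ± 30.8 TPM (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 0.017). UGT85A8, a glycosyltransferase gene, was 5.38 above the median (SE 1.2). Also above it were the cation antiporter gene CHX18 at 5.27 (SE 0.74), a phosphoglycerate mutase-like gene (PGM) at 4.94 (SE 0.65) and the fatty acid conjugase gene FAC2A at 4.92 (SE 1.2). Among the annotated genes the rule could name, falls were largest for MARD1 at -5.34 (SE 0.90) and FLA9 at -4.37 (SE 1.2). A signal peptidase subunit gene (At5g27430) followed at -4.16 (SE 1.2). The microtubule-associated CLASP stood at -4.13 (SE 0.92) and a gene with a carbohydrate binding domain (CBM49) at -3.84 (SE 0.98). Of the cell cycle genes 36 of 315 fell and 6 rose (65 and 14 adjusted over the list alone), and of the cell wall genes 35 of 203 fell and 6 rose (51 and 8 adjusted over the list alone). Of the sugar genes 20 of 102 rose and 4 fell (33 and 14 adjusted over the list alone), and of the ginsenoside genes 2 of 46 fell and none rose (0 and 0 adjusted over the list alone).

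At that day 3736 genes were called, 1816 higher and 1920 lower (48.6% higher); 59.5% were higher after quantile normalization and 61.3% after median ratio scaling. Camera called as higher the clock (1.3e-09), dehydrin (3.1e-07), cold transcription factor (0.00067), sugar (0.002), abscisic acid (0.021) and desaturase (0.04) lists, and none with an estimated correlation (adjusted p = 0.37 to 0.52). It called as lower the cell wall (0.00051), cell cycle (0.001), ribosomal (0.0023), ginsenoside (0.0078), auxin and cytokinin (0.021) and xylem (0.04) lists, and none with an estimated correlation (adjusted p = 0.48 to 0.52). Relative to all genes the xylem marker list had a median of -0.634, beside -0.48 for the cell wall list, and the desaturase list, lower at day 6, had 0.215. Without 1 library the count was 12 (cold day 4 replicate 2), 46 (cold day 4 replicate 1), 84 (control day 4 replicate 1) and 115 (control day 4 replicate 2). All 10 named genes lost their call without control day 4 replicate 2 or either cold day 4 library (highest adjusted p per gene 0.088 to 0.22; limma, Benjamini-Hochberg). All but PGM also lost it without control day 4 replicate 1. Summed by Swiss-Prot hit, MARD1 (adjusted p = 0.21) and At5g27430 (0.12) were not called (limma, Benjamini-Hochberg). The count was 854 when only the 4 libraries of that day were fitted and 8834 with array weights.

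At day 6, the 5 annotated genes named by the rule as rising most were 2 dioxygenase genes, 2 retrotransposon polyprotein genes and a mandelonitrile lyase-like gene. A gene similar to the DNA and RNA repair dioxygenase alkB (At1g11780, TRINITY_DN30555_c1_g1) went from 9.12 ± 6.17 to 834 ± 444 TPM (SD, n = 2), a log2 difference of 6.41 (SE 0.62; limma, Benjamini-Hochberg adjusted p = 0.003). The dioxygenase gene At5g05600 rose by 5.85 (SE 0.60) and a mandelonitrile lyase-like gene (At1g73050) by 5.62 (SE 0.61). A retrovirus-related Pol polyprotein gene (TRINITY_DN35052_c2_g1) rose by 5.41 (SE 0.77) and a Copia protein gene (GIP) by 4.97 (SE 0.79). The intracellular ribonuclease gene RNALX fell from 249 ± 31.4 to 21.4 ± 5.65 TPM (SD, n = 2), a log2 difference of -3.50 (SE 0.46). TBL43, of a family that acetylates wall polymers, stood at -3.49 (SE 0.45), the basic 7S globulin gene BG at -3.25 (SE 0.62), and the glycosyltransferase genes UGT76A2 and CGT at -3.17 (SE 0.54) and -3.04 (SE 0.50). Of the sugar genes 4 of 102 rose and none fell (16 and 3 adjusted over the list alone), and of the dehydrins 2 of 29 rose (5 and 0 adjusted over the list alone). Of the glutathione S-transferases 2 of 24 rose (7 and 1 adjusted over the list alone), and of the cell cycle genes 2 of 315 fell (4 rose and 43 fell adjusted over the list alone). No desaturase or phospholipase gene was called (0 rose and 8 fell adjusted over the list alone), and the list lay below other genes with a median of -0.781 (camera adjusted p = 4.3e-06, and adjusted p = 0.44 with an estimated correlation).

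At that day 216 genes were called, 142 higher and 74 lower (65.7% higher). Camera called as higher the dehydrin (0.00023), sugar (0.00025), clock (0.003), glutathione S-transferase (0.013), abscisic acid (0.015) and cold transcription factor (0.042) lists, and none with an estimated correlation (adjusted p = 0.44 to 0.54). It called as lower the desaturase (4.3e-06), cell cycle (4.3e-05), cell wall (0.00025) and heat shock (0.033) lists, and none with an estimated correlation (adjusted p = 0.44 to 0.46). Without 1 library the count was 1 (cold day 6 replicate 2), 21 (control day 6 replicate 2), 26 (control day 6 replicate 3), 50 (cold day 4 replicate 2), 51 (cold day 4 replicate 1), 93 (either cold day 2 library), 374 (control day 2 replicate 3) and 378 (control day 2 replicate 1). All 10 named genes lost their call without cold day 6 replicate 2 (adjusted p 0.071 to 0.36; limma, Benjamini-Hochberg). Without control day 6 replicate 2 adjusted p was 0.06 for At1g73050, 0.12 for the Pol gene and 0.11 for RNALX, and without control day 6 replicate 3 it was 0.066 for the Pol gene, 0.06 for RNALX and 0.06 for TBL43 (limma, Benjamini-Hochberg). GIP, BG, UGT76A2 and CGT lost their call in 5 to 10 of the 12 fits. Summed by Swiss-Prot hit, At5g05600 (adjusted p = 0.83), the Pol gene (0.13), GIP (0.066) and BG (0.11) were not called (limma, Benjamini-Hochberg). The count was 143 after quantile normalization, 33 without the variance trend, 11 without both cold libraries that stood apart and 0 when only the 4 libraries of that day were fitted.

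**Figure D3:**
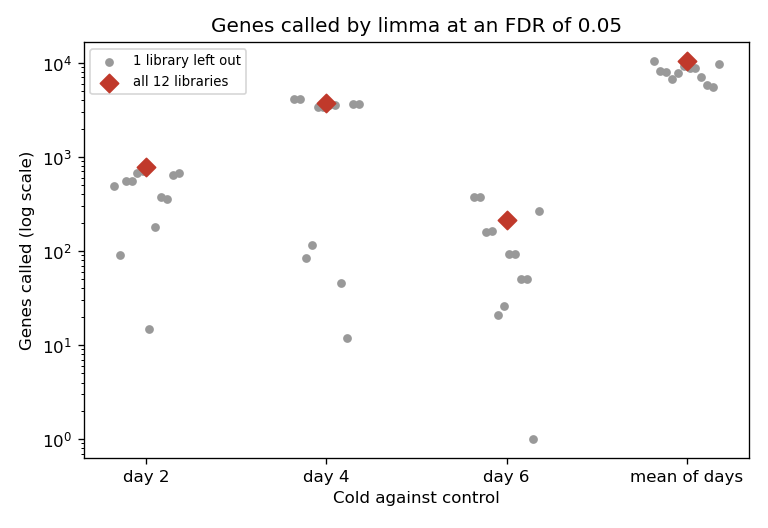
Number of genes called by limma at a false discovery rate of 0.05 (log scale) for cold against control at each day and for the mean of the days, with all 12 libraries (diamonds) and with each library left out in turn (grey points). Leaving out cold day 6 replicate 2 gives 1 gene at day 6, and the mean of the days stays between 5586 and 10384.

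The calls of different days overlapped more than independent lists would, in comparisons that used separate libraries for both temperatures but shared 1 estimate of the spread. Of the genes that rose, 288 were shared by days 2 and 4 (26.8 for independent lists), 85 by days 4 and 6 (5.78) and 25 by days 2 and 6 (2.09). Of those that fell, 64 were shared by days 2 and 4 (5.51), 43 by days 4 and 6 (3.19) and 5 by days 2 and 6 (0.212). Across all genes the log2 differences correlated with Pearson r = 0.533 for days 2 and 4, 0.526 for days 4 and 6 and 0.381 for days 2 and 6; genes are not independent replicates.

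The test of whether the cold effect differed between days called 7 genes, with 4232 at an unadjusted p under 0.05. CML28 was at 124 ± 6.6 TPM in cold against 11.8 ± 1.21 TPM in control at day 2, and at 19 ± 3 against 23.2 ± 10.1 TPM at day 6 (SD, n = 2; log2 differences 3.29 and -0.22; limma, Benjamini-Hochberg adjusted p = 0.04). ACA12 (TRINITY_DN15816_c0_g2), a calcium pump gene of the plasma membrane, behaved alike, with log2 differences of 3.14 at day 2 and -1.40 at day 6 (adjusted p = 0.046; limma, Benjamini-Hochberg). The phosphatase 2C gene At3g17090 was 16.3 ± 0.757 against 19.4 ± 4 TPM at day 2 and 257 ± 40.1 against 20.4 ± 1.57 TPM at day 4 (SD, n = 2; adjusted p = 0.04; limma, Benjamini-Hochberg), and CBSX5 went from 1.71 at day 2 to -1.79 at day 6 (adjusted p = 0.034; limma, Benjamini-Hochberg). The cytochrome P450 gene CYP82D47 was not called (adjusted p = 0.052; limma, Benjamini-Hochberg). CML28, ACA12 and CBSX5 kept their call in none of the 12 fits without 1 library and At3g17090 in 1. The count of 7 became 0 in 8 of those fits, 1 without control day 2 replicate 1 or cold day 4 replicate 2, and 3 without control day 2 replicate 3 or cold day 6 replicate 3. The count was 2 with a pseudocount of 0.1 and under either scaling, 20 when genes were summed by Swiss-Prot hit, and 0 without the variance trend or without both cold libraries that stood apart.

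**Figure D4:**
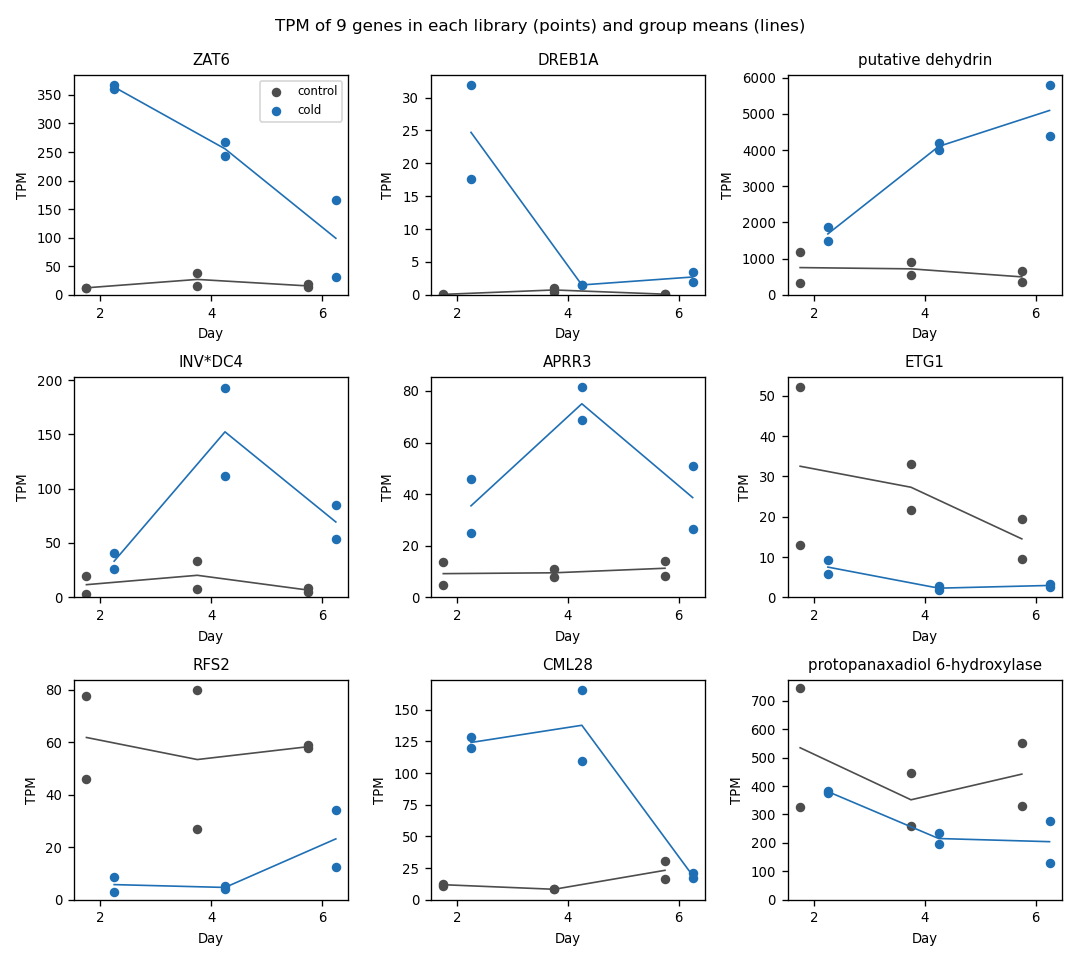
TPM (linear axes from 0) of 9 genes by day in each library, with control and cold drawn beside each other; points are libraries, 2 per group, and lines join group means. ZAT6 lies at 364 TPM in cold at day 2 and 99.1 TPM at day 6, the putative dehydrin averages 3630 TPM over the 6 cold libraries, and CML28 is near its control level at day 6.

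Time in culture without cold was the background for these comparisons. No gene was called as changing over days 2, 4 and 6 in the control calli by limma at a false discovery rate of 0.05. Of 44600 genes 1637 had an unadjusted p under 0.05, a smaller share than 0.05. The 2 controls of a day had r = 0.81, 0.88 and 0.848 at days 2, 4 and 6, against 0.796 to 0.896 between controls of different days. Part of this spread follows the sets of controls that cut across days. With this spread between replicates, the absence of calls does not show that time in culture had no effect. Among the annotated genes the rule could name, the lowest p was for CYP71D312 (TRINITY_DN33832_c0_g1), a cytochrome P450 gene at 29.8 ± 9.09, 3.35 ± 1.15 and 58 ± 21.7 TPM on days 2, 4 and 6 (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 0.22). The polyol transporter gene PLT1, at 32.8 ± 6.8, 42.9 ± 1.56 and 109 ± 21.7 TPM (SD, n = 2), was not called either. Without 1 library the control count was 6 (control day 2 replicate 1), 2 (control day 4 replicate 1) and 1 (control day 2 replicate 3). In the cold calli 268 genes changed over the days. Of genes changing in the cold series, 0 were called without cold day 2 replicate 3, 9 without cold day 2 replicate 1, 11 without either cold day 4 library, 37 without cold day 6 replicate 3, 78 and 79 without control day 4 replicates 1 and 2, and 141 and 162 without control day 6 replicates 3 and 2. For single genes, whether the cold series changed more than the control series was tested only by the day by temperature test given above. For the lists, the cold effect at day 6 was compared with that at day 2. With all 12 libraries only the desaturase list was called, as lower at day 6 (camera adjusted p = 1.2e-09, and adjusted p = 0.79 with an estimated correlation). Of its 85 members, 44 are the delta-12 desaturase genes summed further below. Which other lists were called depended on the libraries. Camera also called glutathione S-transferases without control day 6 replicate 2, for example, and the cell wall list without both cold replicate 3 libraries.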

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

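Of the tests in this part, those of a control library under a cold label, of the profile of cold day 2 replicate 3, of scaling, and of high values in control day 6 replicate 2 were chosen after the result was seen. The fits of the desaturase sum without single libraries, the count of its genes below 0, the comparison of its library sums and the splits for single lists were also chosen after. So were the mixture shares without the TPM minimum or by single controls. The mixture, summed desaturase and other split tests were written down first.

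The cold effect differed between days in 7 genes by the interaction test, and these were picked out for a closer look because that test compares the 3 daily effects directly. By limma with Benjamini-Hochberg adjustment, adjusted p was 0.016 for TRINITY_DN18933_c3_g1, 0.022 for TRINITY_DN18159_c5_g3, 0.034 for CBSX5, 0.04 for At3g17090, 0.04 for CML28, 0.046 for ACA12 and 0.046 for TRINITY_DN14816_c0_g4. Of these, TRINITY_DN18933_c3_g1 and TRINITY_DN18159_c5_g3 have no protein annotation, and TRINITY_DN14816_c0_g4 is annotated as an uncharacterized protein. TRINITY_DN18933_c3_g1 had a mean of 249 TPM in cold at day 2 and 4.54 TPM at day 6. Groups of 2 libraries are too small for a test of single outlying samples.

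Cold day 6 replicate 3 lay nearer to the controls (15.4 on the first component) than its partner (90.6). Control RNA mixed into the library would keep the same share of rises and falls. Over genes called at day 4 with a day 6 control mean of at least 1 TPM, which left out 276 of 1816 rises and 9 of 1920 falls, it kept 57.6% of the falls (95% bootstrap interval over genes 54.7 to 61) and 35.3% of the rises (32.7 to 38.3). The intervals treat genes as independent, which they are not, and do not measure the spread between libraries. With every gene above 0 in those controls the shares were 57.5% and 35.9%, and with single control libraries as reference 53.2 to 70.5% and 32 to 40.3%. This argues against mixing as the whole cause if its cold part is like replicate 2. A control library under a cold label would differ from the day 6 controls in the day 4 direction in about as many genes as not, and it did so in 79% of the genes called at day 4, against 92.9% in replicate 2. A weaker or shorter exposure of these calli remains open and was not tested.

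Calls at day 2 were mostly rises (83.7%). With quantile normalization 71.2% were rises (72.4 to 81.4% in 12 fits that each left out 1 library), so scaling does not account for the whole excess. Without cold day 2 replicate 3, which had the highest median TPM, 75% of 180 calls were rises. Leaving out a further library gave 78.6 to 100% in 8 fits with 1 to 77 calls and no call in 2 others. That library therefore does not account for the whole excess either, though few calls remain. No biological explanation was tested.

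The desaturase and phospholipase D list lay lower at day 6 than other genes (camera adjusted p = 4.3e-06, and adjusted p = 0.44 with an estimated correlation). Without control day 6 replicate 2, whose summed delta-12 desaturase TPM was the highest (9223), camera still gave adjusted p = 0.014. A shift of reads from some near-identical genes to others would leave their sum unchanged. The sum of 44 such genes had a log2 difference of -1.66 at day 6 (-3.15 to -0.177 as 2 SE either side). As 1 gene, the sum was not called (limma, Benjamini-Hochberg adjusted p = 0.28). Of the 44 genes 40 lay below 0, and the sums of both cold day 6 libraries (2074 and 1646 TPM) were the lowest of all 12. These values argue against a shift of reads among these genes as the whole cause. Divided reads could also count 1 fall in many genes of the list, and neither the sum nor the 40 genes can test that. The size of the fall rests on few libraries, since without control day 6 replicate 2 the sum stood at -1.01 (-2.88 to 0.865) with 36 genes below 0, and the interval reached 0 in 4 other fits without a library. No biological explanation was tested.

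For the mean effect, 1 of 100 splits of the libraries within days, the real one, gave as many genes. The real split gave 10384 against at most 2117 in any other split. Only 108 distinct splits exist, so the test is coarse and cannot exclude chance. It treats libraries as independent, so it says nothing on chance differences between cultures if replicates share a culture. For the list tests 31 of 100 splits gave at least the 8 lists called, with 11 as the highest of the others, so chance is not excluded for the number of lists. By list median relative to all genes, 10 of 100 splits lay as far from 0 as the real one for dehydrins (0.58, highest other 1.03) and 5 of 100 for cold transcription factors (0.268, highest other 0.295), so chance is not excluded for these lists. Of the other lists called, 3 of 100 splits did so for heat shock (-0.21, highest other 0.258), 2 for abscisic acid (0.337, highest other 0.398), and only the real one for clock, sugar, cell cycle and cell wall genes. Only the real one did so too for the proline, ethylene and jasmonate, and phenylpropanoid lists, which camera did not call. Camera also did not call the ginsenoside list (2 of 100 splits, -0.271), the epidermis list (2 of 100, 0.569) and the glutathione S-transferase list (4 of 100, 0.305). Both criteria therefore disagree on these lists. The split shares were not adjusted over lists, and 1 of 100 is the lowest that a list could reach. Chance is therefore not excluded for any list, also where only the real split lay as far.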

How the results depend on the processing

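The scalings, the fit without trend, array weights, the fit without both cold replicate 3 libraries and the crossed block were chosen after the results were seen; the other settings were planned. With a pseudocount of 0.1 the counts were 453 at day 2, 2 for the day by temperature test and 159 for days in cold. Same-numbered libraries did not deviate together (correlations of -0.19, 0.0074 and -0.012 at days 2, 4 and 6), so the numbers do not show pairing. With a replicate block within day the counts were 211, 1155 and 35 at days 2, 4 and 6, 6869 for the mean and 0 for day by temperature. With a replicate block across days they were 412, 2204 and 61 at days 2, 4 and 6, 8547 for the mean, 0 for day by temperature and 34 for days in cold, and crossing the numbers at day 2 gave 649 at day 2 and 10017 for the mean. A 2-fold threshold gave 6366 for the mean. The 4 libraries of a day alone gave 0, 854 and 0. Genes summed by Swiss-Prot hit gave 20 for day by temperature, weakened 28 of 120 named gene results, and turned RD21B (TRINITY_DN21748_c0_g1) to 0.504, the glycine-rich RNA-binding TRINITY_DN24783_c1_g1 to 0.356, HSP90-5 (TRINITY_DN18175_c0_g1) to -0.160 and ATJ20 (TRINITY_DN18589_c1_g4) to 0.879. Quantile normalization gave 143 at day 6 and 2 for day by temperature, and median ratio scaling 2 for the latter. Without trend the counts were 1234 at day 2, 33 at day 6 and 0 for day by temperature. Array weights gave 182 at day 2, 8834 at day 4 and 579 for days in cold. With 2 libraries per group the weights were equal within each group, such as 1.63 for both cold day 4 and 0.75 for both cold day 2 libraries. They therefore weighted groups and could not lower the weight of 1 outlying library. Without both cold replicate 3 libraries they were 77 at day 2, 11 at day 6, 0 for day by temperature and 0 for days in cold. Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 15 to 701 at day 2, 12 to 4175 at day 4, 1 to 378 at day 6, 5586 to 10384 for the mean, 0 to 3 for day by temperature, 0 to 6 for days in control and 0 to 369 for days in cold. Camera called 0 lists with an estimated correlation and 8 to 10 without a library, and no list lost its call for the mean effect without any library. Of 130 named gene results, 43 were weaker without cold day 4 replicate 2, the most for any single library, and 40 without both cold replicate 3 libraries. DESeq2, RLE size factors, limma-voom and filters on counts were planned and not run, since TPM holds no counts. The cause was not tested.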

Other observations

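The tests of GO and KEGG sets and the split tests of single lists and of mobile elements were chosen after the results were seen. So were the list tests between days 6 and 2 and the hypotheses in this part.

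Genes of the kinesin complex, the motors that move along microtubules in dividing cells, included 62 of 146 that fell and 3 that rose (camera adjusted p = 3.7e-07, and adjusted p = 0.9 with an estimated correlation). Of 31 genes for unwinding DNA at replication, 17 fell and none rose, with a median log2 difference of -0.861. Of 22 THO complex genes, which take part in export of messenger RNA, 11 fell and none rose, with a median of -0.987. Of 59 genes for docking in nuclear import, 24 fell and none rose.

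Genes annotated with the response to chitin, a set of defence and stress regulators, included 41 of 106 that rose and 12 that fell (camera adjusted p = 5.1e-06, and adjusted p = 0.9 with an estimated correlation). Of 30 genes that restrain ethylene signalling, 15 rose and none fell, and of 25 genes of sucrose metabolism, 12 rose and none fell. Of 890 GO sets camera called 34 as higher and 89 as lower, of 119 KEGG sets 1 as higher and 5 as lower, and none with an estimated correlation (lowest adjusted p 0.9 and 0.91).

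Of 320 genes with transposon annotation, 22 rose and 29 fell for the mean effect. Their median lay at -0.19 relative to all genes, with 0.316 as the farthest of the other splits, and 9 of 100 splits lay as far, so chance is not excluded. The set was not tested at single days.

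CML28 and ACA12 were called higher in cold at days 2 and 4 and not at day 6. The calcium list had 7 rises and no fall at day 2, 4 rises and 5 falls at day 4 and neither at day 6, but all calls were fewer at day 6 (216 against 786 at day 2), and no difference of the list between days 6 and 2 was called (camera adjusted p = 0.45, and adjusted p = 0.79 with an estimated correlation). A hypothesis for these 2 genes alone is that their response fades within 6 days of cold. The day by temperature calls behind it were unstable, with 0 to 3 genes called without a library and 20 when genes were summed by Swiss-Prot hit. Neither gene kept that call in any of the 12 fits without a library (limma, Benjamini-Hochberg adjusted p 0.059 to 0.2 for CML28 and 0.053 to 0.22 for ACA12). A series with at least 4 separate cultures per day, with CML28 and ACA12 measured by quantitative PCR at days 2, 4 and 6, would test it.

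A hypothesis from the lower replication, kinesin and wall genes is that cold calli divide and expand less. Counting cells in S phase by EdU labelling and callus fresh weight at days 2, 4 and 6 would test it. Of the sets behind it, the cell cycle and cell wall lists were fixed with the plan, and only the real one of 100 splits put their medians as far from 0 (-0.34 with 0.313 as the highest other, and -0.526 with 0.431). That share is the lowest the splits can give and was not adjusted over lists, so it does not exclude chance. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.28 and 0.32), and the kinesin set was picked after its result was seen.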
